A study of Homo sapiens with 3 samples.

How the data were processed

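The samples were 3 RNA samples of SKBR3 cells treated for 3 h with ethanol, estradiol or ERα17p, with 1 Affymetrix array each; nothing says whether they came from separate experiments. Groups were taken from the sample labels. The labels do not say what ERα17p was dissolved in, and they name different media for growth and for treatment. Per the labels' protocols, total RNA was isolated on columns, labelled with biotin and hybridised by the manufacturer's procedure. Per the submitters' processing notes, the authors computed the values with RMA, a method that corrects background, normalises by quantiles and summarises the probes of a probe set on a log scale. Its version and software are not given in the sources used here. The deposited values were read as log2, because RMA yields log2 values, although no source names the base.

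The deposited values were not RMA levels. Column medians lay near 0 (-0.02, -0.00 and 0.00 for the arrays labelled vehicle, estradiol and ERα17p), and in 3994 of 54675 probe sets (7.30%) a pair of the 3 columns held exact mirror images around 0, to a tolerance of 1e-06 and counting only values over 0.001. A median over an even number of arrays, larger than these 3, gives such pairs. Each probe set was therefore taken to be centred on a median to which arrays beyond these 3 contributed. What those arrays were is not given in the sources used here, and they were not used here. Differences between the 3 arrays survive such centring, and levels do not. It also means that an array's distance from the baseline depends partly on the other arrays in that median.

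The design fixed before the data were examined could for this reason not be followed in 4 points, each of which needs levels. It planned a filter on dim probe sets, the brightest probe set as a gene's value, random lists matched on mean signal, and a spread at like signal. In their place no filter was set, a gene's value was the median over all its probe sets, random lists were matched on the number of probe sets per gene (1, 2, 3, or 4 and more), and the spread was taken over all genes. Signal over background is unknown for every gene, so that differences of genes that are hardly expressed cannot be told from those of expressed ones, and the small number of arrays limits the precision.

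Probe sets were named through the platform annotation, updated by Entrez gene ID to the gene table of assembly GRCh38.p14. Of the 54675 probe sets, 62 were controls, 41091 had 1 gene symbol, 1801 had several and 11721 were unnamed here. Entrez IDs matched for 41037 of the 41091, and 0 symbols changed. The 41091 gave 19775 genes, of which 10523 had at least 2 probe sets. Controls and probe sets with several or no symbols were left out of gene values.

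Comparisons were log2 differences between 2 arrays: estradiol minus vehicle, ERα17p minus vehicle, and estradiol minus ERα17p. With 1 array per group there was no test, and genes were counted by the fixed rule of 1.5-fold. The 30 gene lists were written before the data were examined. A list's median difference was placed among those of 10000 random lists of as many genes. It was said to stand apart at or below percentile 2.5 or at or above 97.5, which describes these arrays and is not a test. By that rule 1.5 of 30 lists of randomly drawn genes stand apart per comparison. Genes of a list can move together between single cultures, so 1.5 does not measure chance differences between cultures. Lists overlap in part. In all, 90 list percentiles were computed for the comparisons and 90 for single arrays against the baseline, besides those of the alternatives. Named genes were, per comparison, the 8 with the largest difference each way (5 for estradiol against ERα17p), the 5 each way with the largest mean difference among genes whose probe sets all moved alike (3 for estradiol against ERα17p), up to 4 members of each list with the largest absolute difference, and 5 receptor genes. Genes known only by a locus number were counted and not named. A few other list members were named after their values were seen, where a count of called members was spelled out or one gene was followed through several arrays or lists.

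The variance of gene differences was split among the 3 arrays from the 3 pairwise variances, on the assumption of independent deviations, which did not hold. For the array shared by both treatments, chance values came from 1000 shuffles of each array's deviations among genes. On simulated arrays for estradiol against vehicle (19775 genes, with noise taken from the difference between both treated arrays), the size rule found 38 of 67 genes changed by exactly 1.5-fold, 67 of 67 changed 2-fold and 66 of 66 changed 4-fold, and it passed 37 of 19550 unchanged genes. For ERα17p against vehicle, 50 of 19775 genes passed between unchanged arrays. The difference that gave the noise had a spread of 0.13 log2 units over all genes. Differences from the array labelled vehicle had 0.20 with estradiol and 0.17 with ERα17p. If that array was noisier, the simulated recovery and the counts of unchanged genes are too favourable for comparisons with it. Alternatives were median centring of each array, a 2-fold rule, leaving out probe sets with names in _s_at or _x_at, which can take up several transcripts, and the mean in place of a list's median. Others were chosen after seeing the data: the mean over probe sets, 1.5-fold on every probe set, 3 times the spread, and the authors' baseline in place of the array labelled vehicle. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.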

Results

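Gene expression was measured in SKBR3, an established human breast cancer line with ERBB2 amplification and luminal traits, known for lacking oestrogen receptor α and for carrying the G protein-coupled oestrogen receptor GPER1. After 4 h in medium with charcoal-stripped serum, which is depleted of steroid hormones, the cells received 0.1% ethanol as vehicle, 1 µM estradiol, or 1 µM ERα17p, a synthetic peptide copied from the sequence of oestrogen receptor α. RNA was taken 3 h later. Each condition had 1 whole-genome array, 3 arrays in all, so that no difference below has a replicate check, an error or a p-value. The series title speaks of a time course, whereas every sample is labelled 3 h. The design asks which genes answered early to estradiol, which to the peptide, and whether both answers were alike. Values covered 54675 probe sets and, through those with 1 gene symbol, 19775 genes. They are distances from a baseline that the authors subtracted from each probe set, so that arrays can be compared gene by gene but expression levels cannot be read. Their log base is not given in the sources used here and was taken as 2, the base that the RMA method yields. "Higher" and "lower" below mean a difference of at least 1.5-fold (0.585 on the log2 scale).

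The array labelled vehicle stood apart from both others. On it, genes of the inflammatory NF-kB programme lay far above the authors' baseline, led by the chemokine genes CCL20 (7.12 log2 units), CXCL8 (6.93) and CXCL1 (6.10), the adhesion molecule gene SELE (5.61) and the cytokine gene TNF (5.30). In all, 465 genes lay at least 1.5-fold above the baseline on this array and 60 below it. The estradiol array had 1 gene above and 10 below, and the ERα17p array 13 above and 1 below. The standard deviation over probe sets was 0.27 log2 units on the array labelled vehicle, 0.12 on the estradiol array and 0.13 on the ERα17p array. Had the 3 arrays deviated independently, the array labelled vehicle would have held 73.0% of the variance of the gene differences, the estradiol array 23.6% and the ERα17p array 3.48%. Both treated arrays had near-equal standard deviations, against that split between them, so the assumption did not hold. The 3′ minus 5′ difference of ACTB, a sign of RNA integrity, was 0.30 on the array labelled vehicle against 0.02 and -0.04 on the estradiol and ERα17p arrays. For GAPDH it was 0.05, 0.01 and -0.03. Hybridization spikes had medians of -0.00 on the array labelled vehicle, -0.10 on the estradiol array and -0.24 on the ERα17p array. The 27 Bacillus control probe sets had medians of 0.13, -0.07 and -0.03 in the same order.

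**Figure D1:**
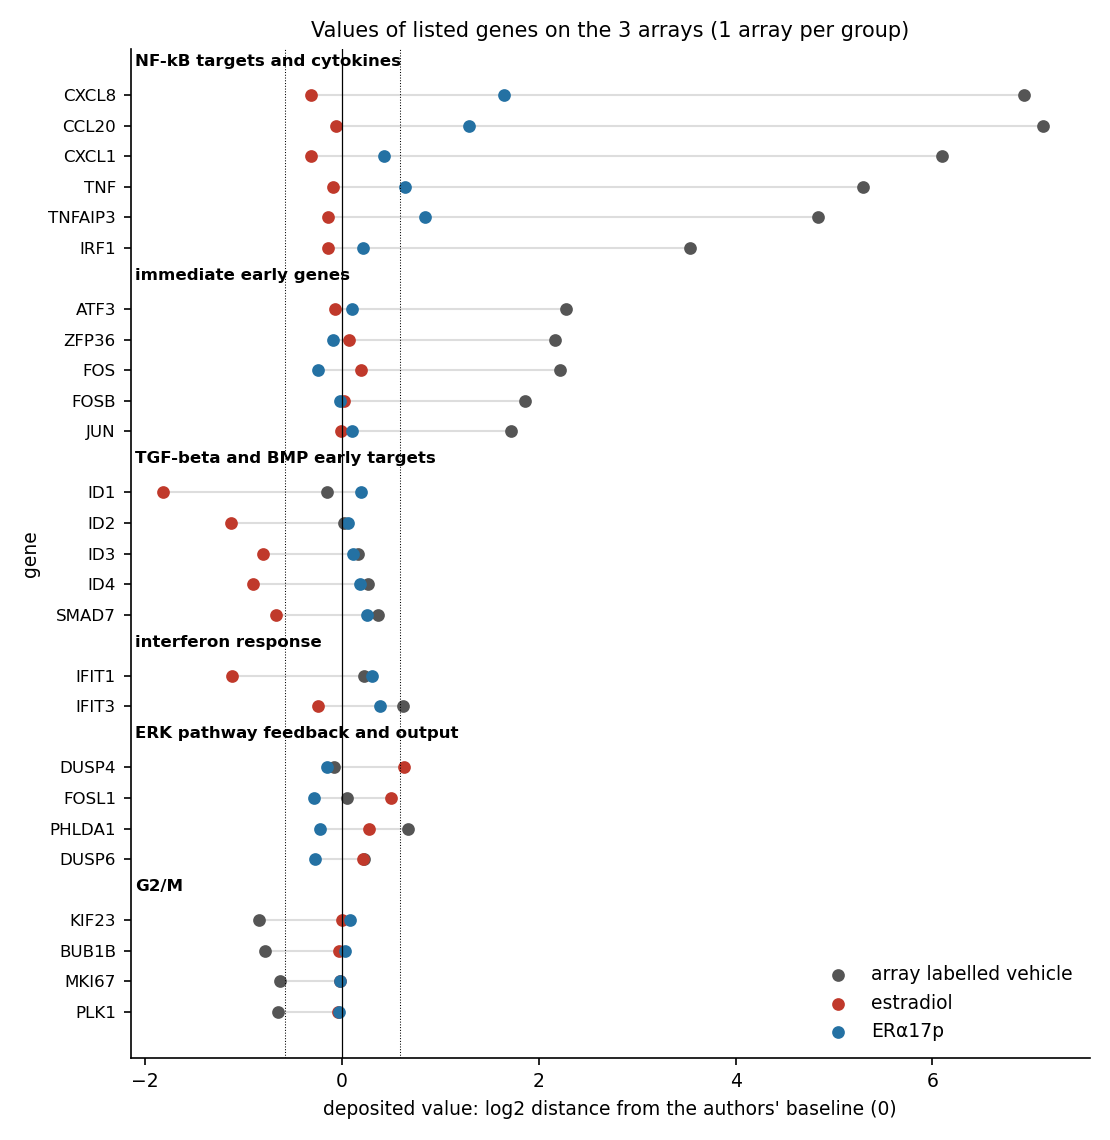
Deposited values of 26 listed genes on the 3 arrays, as log2 distance from the authors' baseline at 0, with 1 point per array and dotted lines at 1.5-fold. CXCL8 and CCL20 lie at 6.93 and 7.12 on the array labelled vehicle and at -0.31 and -0.06 on the estradiol array, whereas ID1 lies at -1.82 on the estradiol array and within 0.20 of the baseline on both others.

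Estradiol was first compared with the array labelled vehicle. Among genes with a symbol, the widest differences were those of genes lower on the estradiol array: CXCL8 by -7.24 log2 units (152-fold), CCL20 by -7.19, CXCL1 by -6.41, SELE by -5.66, TNF by -5.38, the NF-kB feedback gene TNFAIP3 by -4.98, the chemokine gene CXCL3 by -3.90 and the transcription factor gene IRF1 by -3.68. Fewer genes were higher, and by less. They were led by DKK1, which encodes a Wnt antagonist (2.83-fold), the aquaporin gene AQP11 (1.30 log2 units), LRRC32 (0.96), the trefoil factor gene TFF2 (0.95), ITPR1-DT (0.95) and PSRC1, a spindle gene (0.89), each read by 1 probe set. In all, 579 genes were lower and 160 higher, of which 177 and 2 passed 2-fold. Among genes whose probe sets all moved the same way, PMAIP1, a pro-apoptotic gene, and PPP1R15A, a stress phosphatase gene, followed CXCL8, TNFAIP3 and IRF1 with -3.09 and -3.03. On the higher side, CCNF (cyclin F) had 0.88, KIF23, a motor gene of cell division, 0.85, SLITRK6 0.84, TRIL 0.77 and CISH 0.76.

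Of 30 gene lists fixed before the data were examined, 12 stood outside the central 95% of random lists in this comparison. Lists of randomly drawn genes give 1.5. In the NF-kB and cytokine list 17 of 22 measured genes were lower and none was higher, with a median of -1.63. Immediate early genes, which respond first to a stimulus, were lower in 15 of 28 cases (median -0.80). Among them were ATF3 (-2.35), ZFP36 (-2.09), FOS (-2.02) and FOSB (-1.85). The 3 probe sets of ATF3 ran from -3.57 to 0.04. Of 15 genes reported to respond to GPER in breast cancer cells, 11 were lower (median -1.46), led by TNF, ATF3 and RGS2 (-2.18). That list shares 8 genes with the immediate early list. Early TGF-β and BMP targets were lower in 13 of 20 cases (median -0.93), with BAMBI at -1.70, ID1 at -1.67 and JUNB at -1.65. Each of these 4 lists lay at percentile 0 of the random lists. So did the interferon response, with 7 of 24 genes lower (median -0.26, IFIT1 -1.34, IFIH1 -0.95). AhR and NRF2 targets did so too, with 4 of 17 lower and CYP1A1 higher at 0.67 (median -0.30, HMOX1 -2.61, SLC7A11 -1.56). The 3 probe sets of SLC7A11 ran from -1.63 to 0.04.

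Stress and growth lists were also low. They comprised ATF4 and unfolded protein response genes (9 of 24 lower, median -0.14, percentile 0.05; CHAC1 -2.68, SESN2 -1.94), apoptosis regulators (6 of 26, -0.15, percentile 0.01; TNFRSF10B -0.85, BCL2L11 -0.83) and p53 targets (7 of 17, -0.16, percentile 0.13; GADD45A -2.43, CDKN1A -1.98). Genes of cholesterol and fatty acid synthesis (5 of 22, -0.10, percentile 0.70; HMGCS1 -1.05, INSIG1 -0.89) left that range, at percentile 4.19, without probe sets that can take up several transcripts. ERK pathway feedback and output genes were lower in 6 of 20 cases (median -0.09, percentile 1.45; MAFF -2.20, DUSP5 -1.27, SPRY4 -1.07), while DUSP4, an ERK phosphatase gene, was higher by 0.72. Only the G2/M list lay high: 4 of its 25 genes were higher (KIF23 0.85, BUB1B 0.75, MKI67 0.60, PLK1 0.60), all 25 lay above 0, and the median was 0.38 (percentile 100). EGF family ligands and shedding enzymes, hypoxia and glycolysis, and YAP and SRF targets lay at percentiles 23.9, 25.3 and 3.22. With the mean in place of a list's median they came to stand apart low, at 2.18, 1.01 and 1.47. The EGF family list did so too, at 0.58, without probe sets that can take up several transcripts.

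The array labelled vehicle itself lay at least 1.5-fold above the baseline in 450 of these 579 lower genes and below it in 44 of the 160 higher ones. With the baseline in its place, the estradiol array had 10 lower genes and 1 higher (9.09% of calls higher in place of 21.7%), of which 8 and 1 are also among the genes called against the array labelled vehicle. The NF-kB, interferon, TGF-β and BMP, ATF4, apoptosis and cholesterol lists stayed low, at percentiles from 0 to 1.82, but by smaller medians. The NF-kB list had a median of -0.06 with 0 of 22 genes lower. Against the array labelled vehicle it had -1.63 and 17 of 22. TGF-β and BMP targets had -0.17 (5 of 20 lower) and interferon genes -0.09 (1 of 24). The ATF4, cholesterol and apoptosis lists had -0.05, -0.04 and -0.03, with 0 genes lower in each. The immediate early and ERK lists turned high at 97.95 and 100, and the G2/M (8.65), GPER (13.3), p53 (4.66) and AhR and NRF2 (17.5) lists came within the central range.

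The ERα17p array, set against the same array labelled vehicle, was also lower in cytokine and chemokine genes. CCL20 differed by -5.83 log2 units, CXCL1 by -5.67, CXCL8 by -5.28, SELE by -5.11, TNF by -4.65, CXCL3 by -4.13, TNFAIP3 by -3.99, IRF1 by -3.33, PPP1R15A by -2.93 and PMAIP1 by -2.53. On the higher side stood AQP11 (1.09), DKK1 (1.02), PSRC1 (0.95), KIF23 (0.93), DEPDC7 (0.91), CCNF (0.91), CKAP2L, another spindle gene (0.90), TRIL (0.82), CALHM2 (0.81) and SLC40A1, which encodes the iron exporter ferroportin (0.76). In all, 424 genes were lower and 115 higher, and 146 and 3 passed 2-fold.

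Of the 30 lists, 10 stood outside the central range with the peptide. NF-kB and cytokine genes were lower in 18 of 22 cases (median -1.24), GPER-responsive genes in 11 of 15 (-1.35; TNF -4.65, FOS -2.46), immediate early genes in 15 of 28 (-0.66; ZFP36 -2.25, ATF3 -2.18) and ERK feedback and output genes in 7 of 20 (-0.32; MAFF -2.44, EGR1 -1.49), all at percentile 0. The AhR and NRF2 list had 4 of 17 genes lower (-0.17, percentile 0.01; HMOX1 -1.45), the TGF-β and BMP list 6 of 20 (-0.10, percentile 0.41; JUNB -1.35, BAMBI -1.25) and the apoptosis list 6 of 26 lower and 1 higher (-0.06, percentile 0.96). Less far out lay the EGF family ligands and shedding enzymes, with 2 of 12 lower (percentile 1.84; EREG -1.05, HBEGF -0.64), and hypoxia and glycolysis, with 4 of 26 lower and 1 higher (percentile 2.30; PFKFB3 -1.04, BHLHE40 -0.95). Both came within the central range, at 9.56 and 55.2, without probe sets that can take up several transcripts. Probe sets of EREG and HBEGF disagreed in sign with estradiol against the array labelled vehicle (-2.17 to 0.29 and -1.75 to 0.02). Of the other lists that were low with estradiol, ATF4 (8 of 24 lower, percentile 2.89) and p53 (6 of 17, percentile 5.16) came to stand apart at percentiles 0 and 0.02 with the mean in place of a list's median. ATF4 did so at 0 without probe sets that can take up several transcripts, and p53 at 1.91 with the mean over probe sets. Interferon response (1 of 24 lower, percentile 12.02) did so at 0.28 with the mean over probe sets. Cholesterol and fatty acid synthesis (2 of 22 lower) lay at 15.5. The G2/M list was again high, with 8 of 25 genes higher, all 25 above 0 and a median of 0.50 (percentile 100; KIF23 0.93, BUB1B 0.81, NDC80 0.78, CENPA 0.72). G1/S and DNA replication genes (percentile 91.5) came to stand apart high, at 99.12, with the mean in place of a list's median.

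Here the array labelled vehicle lay at least 1.5-fold off the baseline in 375 of the 424 lower and 48 of the 115 higher genes. Against the baseline the ERα17p array had 13 higher genes and 1 lower, so that 92.9% of calls were higher in place of 21.3%. Of the 13, 4 were also higher against the array labelled vehicle, whereas the other 9 were lower against it, CCL20, CXCL8, TNF and TNFAIP3 among them. The 1 lower gene did not pass 1.5-fold against it. The NF-kB (99.98), TGF-β and BMP (99.96) and GPER (98.6) lists turned high, by medians of 0.09, 0.08 and 0.06. Of their genes, 5 of 22, 0 of 20 and 1 of 15 were higher. The ERK list stayed low (0.41, median -0.04), and the other 6 came within the central range.

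Both sets of differences share 1 array and cannot be read as separate evidence. Across 19775 genes, which are not independent replicates, they had a Pearson correlation of 0.849 and a Spearman correlation of 0.709. Shuffling each array's deviations among genes, so that only the shared array remained, gave a Pearson correlation of 0.869 on average over 1000 draws. The covariance was 0.0693, and 0.0726 in the shuffled arrays. Genes lower in both comparisons numbered 381 (403 with shuffled arrays, 12.4 for independent lists), and genes higher in both numbered 47 (48.3 and 0.930). A single control array cannot be split. The shuffled arrays, which share only that array, gave at least as much as was observed in the Pearson correlation, the covariance and both counts. Values are distances from a baseline, so a lowering common to both treatments could appear as height on the array labelled vehicle. The shuffle would keep that height, so it cannot tell a common response from the shared array and does not count against one. The Spearman correlation was not computed on them. With the baseline as reference the correlation was -0.17.

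**Figure D2:**
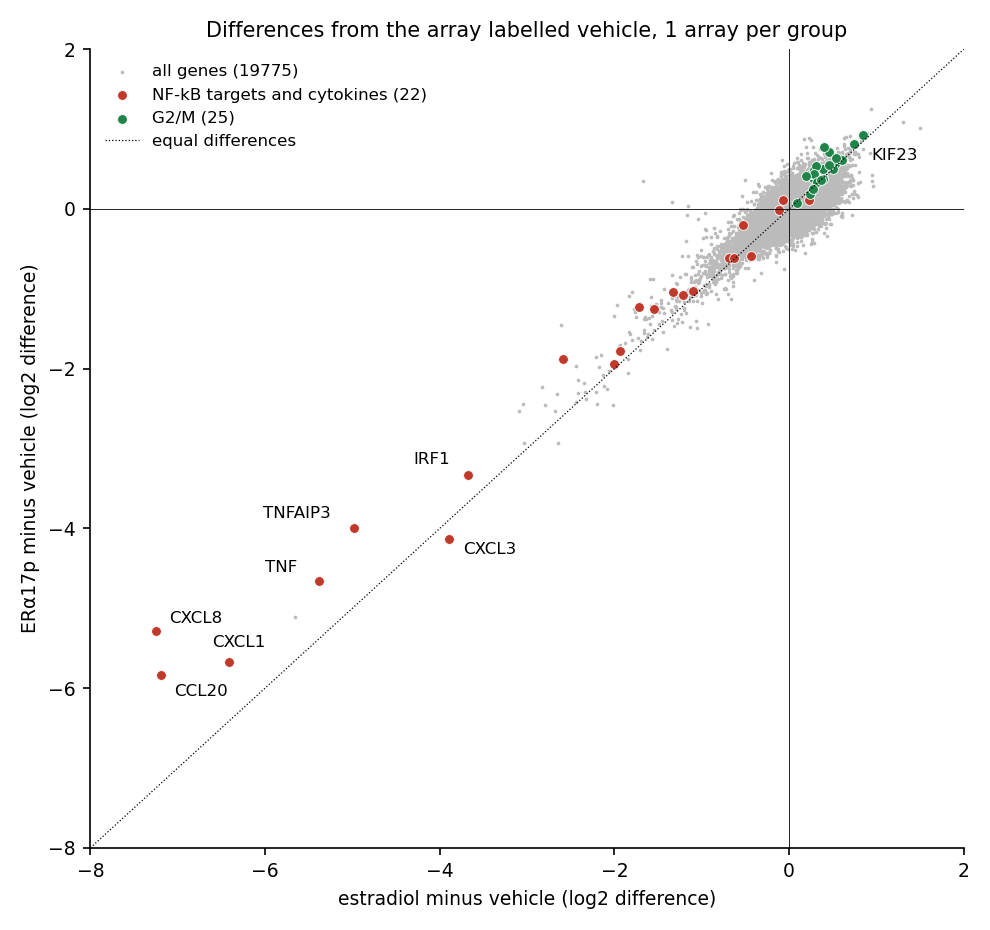
Log2 difference of each of 19775 genes from the array labelled vehicle, for estradiol (horizontal) and ERα17p (vertical), with NF-kB and cytokine genes in red, G2/M genes in green and a dotted line of equal differences. Both axes share 1 array; CXCL8 lies at -7.24 and -5.28, and KIF23 at 0.85 and 0.93.

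Estradiol was then compared directly with ERα17p, which does not involve the array labelled vehicle. The lower genes on the estradiol array were led by ID1 (-2.02, or 4.06-fold), CXCL8 (-1.96), the interferon-induced gene IFIT1 (-1.42), CCL20 (-1.35) and ID2 (-1.19). The ID genes encode inhibitors of helix-loop-helix transcription factors and are immediate targets of BMP signalling. Genes higher with estradiol were led by DUSP4 (0.79), the AP-1 gene FOSL1 (0.78), MATR3 (0.74), SIT1 (0.71) and LILRA4 (0.71). Among genes with all probe sets moving alike, TNFAIP3 had -0.98, TENT5C 0.61 and the mucin gene MUC5B 0.50. In all, 41 genes were lower and 29 higher, and 7 and 0 passed 2-fold.

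By list, early TGF-β and BMP targets were lower in 5 of 20 cases (median -0.32, percentile 0), namely ID1, ID2, ID4 (-1.09), SMAD7 (-0.93) and ID3 (-0.92). These 5 were also lower on the estradiol array than on the array labelled vehicle, by -1.67, -1.16, -1.17, -1.05 and -0.96, and than the baseline. NF-kB and cytokine genes were lower in 6 of 22 cases (median -0.24, percentile 0), namely CXCL8, CCL20, TNFAIP3, CXCL1 (-0.74), TNF (-0.73) and CCL2 (-0.71). All 6 lay above the baseline on the ERα17p array, at 1.65, 1.29, 0.84, 0.43, 0.64 and 0.91. Interferon response genes were lower in 2 of 24 cases, IFIT1 and IFIT3 (-0.63), with 2 of 24 above 0 (median -0.18, percentile 0). The ERK feedback and output list lay high: DUSP4 and FOSL1 were higher, 18 of 20 genes lay above 0, and the median was 0.21 (percentile 100; PHLDA1 0.49, DUSP6 0.49, EGR1 0.44). The p53 list (1 of 17 lower, CDKN1A -0.78; percentile 0.06) and the ATF4 list (1 of 24, SLC7A11 -0.69; percentile 0.24) lay low by small medians of -0.13 and -0.10.

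Another 5 lists lay low as well but lost that place under another setting. Cholesterol and fatty acid synthesis (0 of 22 lower, median -0.13, percentile 0), YAP and SRF targets (0 of 22, -0.11, percentile 0.07), G1/S and DNA replication (0 of 25, -0.07, percentile 2.35) and AhR and NRF2 targets (2 of 17, -0.09, percentile 2.24; HMOX1 -1.16) moved to percentiles of 15.9, 3.00, 4.97 and 41.9 without probe sets that can take up several transcripts. The GPER-responsive list (1 of 15, -0.11, percentile 1.08) moved to 2.54 with the mean over probe sets. Conversely, the G2/M list (percentile 6.39) came to stand apart low, at 0.61, with the mean in place of a list's median. Probe sets of 1 gene matched each other weakly in this comparison (r = 0.15 over 10523 genes, against 0.47 and 0.46 in the comparisons with the array labelled vehicle). Where the first of a gene's probe sets passed 1.5-fold, the second had the same sign in 32 of 54 cases (59.3%), against 80.9% and 80.2%.

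**Figure D3:**
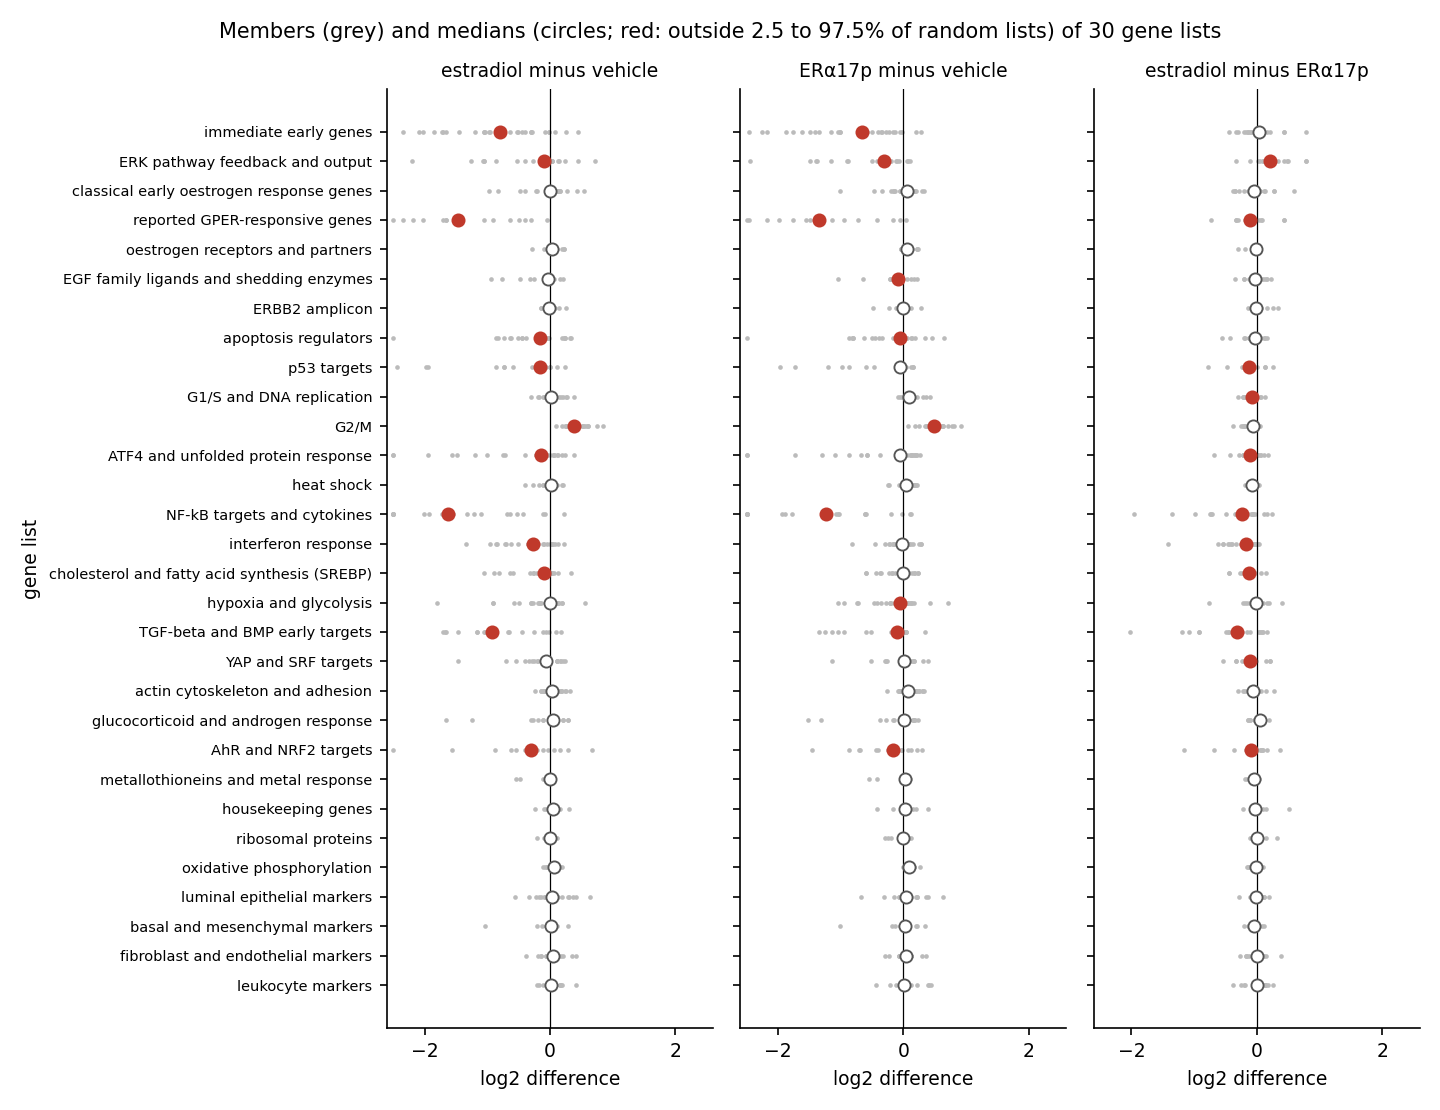
Log2 differences of the members (grey, drawn at 2.5 or -2.5 where they lie beyond) and the median (circle) of 30 gene lists in the 3 comparisons, red where the median lies outside the central 95% of 10000 random lists. NF-kB and cytokine genes have medians of -1.63, -1.24 and -0.24, and G2/M genes 0.38, 0.50 and -0.06.

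Classical early oestrogen response genes did not stand apart in any comparison, at percentile 23.2 for estradiol against the array labelled vehicle, 68.5 for ERα17p and 13.5 for estradiol against ERα17p. Of 31 measured genes, EGR3 (-0.97) and HSPB8 (-0.82) were lower with estradiol against the array labelled vehicle, EGR3 was also lower with ERα17p (-1.01), and TFF1 was higher against ERα17p (0.59) but not against the array labelled vehicle (0.54). Differences of the receptor genes ESR1, ESR2, GPER1, EGFR and ERBB2, taken from medians over probe sets, lay between -0.18 and 0.14 in all 3 comparisons. Single probe sets spread wider. With estradiol against the array labelled vehicle, the 9 of ESR1 ran from -0.38 to 0.66 and the 6 of ESR2 from -0.33 to 0.37. Another 13 lists stayed within the central range in all 3 comparisons: receptors for oestrogen and their partners, the ERBB2 amplicon, heat shock, actin cytoskeleton and adhesion, glucocorticoid and androgen response, metallothioneins, housekeeping genes, ribosomal proteins, oxidative phosphorylation, and luminal, basal, fibroblast and endothelial, and leukocyte markers. Together these 14 lists had medians from -0.07 to 0.08 and percentiles from 2.89 to 96.4. With the mean in place of a list's median, glucocorticoid and androgen response came to stand apart at percentiles 2.21 with estradiol and 0.76 with ERα17p, and actin cytoskeleton and adhesion at 99.33 with ERα17p. The latter also did so, at 97.52, with the mean over probe sets. A few members still passed 1.5-fold against the array labelled vehicle, such as SGK1 (-1.66 with estradiol, -1.52 with ERα17p), ERRFI1 (-1.24 and -1.32) and SNAI1 (-1.03 and -1.01).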

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

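The design has no group large enough to test a sample as an outlier and no contrast measured in several settings. Signals outside the comparisons were sought among probe sets that are unnamed here and so entered no gene value. On the estradiol array 14 of them stood above the array labelled vehicle by 1 log2 unit or more, and on the ERα17p array 4, by at most 1.17. Of the 14, 11 differed by 1.03 to 1.38 and lay below the baseline on the array labelled vehicle (-1.18 to -0.48). The other 3, which passed a bar of 1.5 log2 units set after the data were seen, differed by 6.33, 2.39 and 1.92. Each of these 3 lay near the baseline on the array labelled vehicle (0.02, -0.00 and 0.10) and on the ERα17p array (-0.03, 0.00 and -0.22). All 3 are of the kind that can take up several transcripts, and no explanation was tested.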

How the results depend on the processing

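The baseline in place of the array labelled vehicle, 3 times the spread, 1.5-fold on every probe set and the mean over probe sets were chosen after seeing the data, as were centring and leaving out _s_at and _x_at probe sets for the lists. The 2-fold rule left 2 higher and 177 lower genes for estradiol against vehicle, 3 and 146 for ERα17p against vehicle, and 0 and 7 for estradiol against ERα17p. Asking for 1.5-fold on every probe set, among genes with 2 or more, left 6 and 110, 9 and 74, and 1 and 3. Both rules ask for more by construction. At 3 times the spread, a lower bar in the last 2 comparisons (0.59, 0.52 and 0.40 log2 units), ERα17p had 199 higher genes against vehicle, and estradiol against ERα17p had 266 higher and 205 lower, so that 56.5% of calls were higher in place of 41.4%. With the baseline as reference, estradiol had 1 higher and 10 lower genes and ERα17p 13 and 1. The correlation of both treatments then became -0.17. The array labelled vehicle was then no longer the reference, although it entered the median that forms the baseline. In addition, 5 list percentiles reversed, with medians from 0.02 to 0.14 against the baseline. They were those of immediate early (97.95) and ERK (100) genes for estradiol, and of GPER-responsive (98.6), NF-kB (99.98) and TGF-β and BMP (99.96) genes for ERα17p. Of those 60 list percentiles, 39 kept their place. Without _s_at and _x_at probe sets 78 of 87 list percentiles kept their side, 7 lost their place and 2 gained one, and the 3 of metallothioneins were not obtained, with under 5 genes left; 7 lists in place of 11 stood apart for estradiol against ERα17p, and probe sets of 1 gene correlated at 0.33, 0.32 and 0.0943 in place of 0.47, 0.46 and 0.15; the cause was not tested. The mean over members kept 80 of 90 list percentiles on their side (the other 10 came to stand apart) and the mean over probe sets 85 of 90. Centring kept all 90, but it shifts all genes of an array by 1 constant. It could not have changed these percentiles and is no check of them. Of values of named genes, 378 stayed within the spread under centring and 12 moved, and none reversed under centring, the mean over probe sets or without _s_at and _x_at probe sets. Quantile and cyclic loess normalization, both filters on dim probe sets, the brightest probe set and the spread at like signal were not run, because levels are centred out; a pseudocount does not apply to log values. Leaving out a replicate is impossible with 1 array per group. No paired analysis was possible because each group has 1 array.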

Other observations

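Beyond the lists, the array labelled vehicle held further genes far above the baseline; the genes named here were chosen after their values were seen. They include the interferon-induced chemokine gene CXCL10 (2.80), the bacterial sensor gene NOD2 (2.55), the acute phase gene SERPINA3 (2.53), the stress kinase gene PLK2 (2.52), the chemokine gene CX3CL1 (2.45), the activin subunit gene INHBA (2.40), the urokinase gene PLAU (2.23) and the surface marker gene CD83 (2.14). On the estradiol array the same genes lay between -0.50 and 0.19, and on the ERα17p array between -0.07 and 0.57. SELE, a gene best known from activated endothelium, lay at 5.61 on the array labelled vehicle, while fibroblast and endothelial markers did not stand apart.

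Against the authors' baseline, the ERα17p and estradiol arrays lay on opposite sides in several lists, by small medians. Interferon response genes had medians of 0.12 with ERα17p and -0.09 with estradiol (percentiles 100 and 0), TGF-β and BMP targets 0.08 and -0.17 (99.96 and 0), cholesterol and fatty acid synthesis 0.06 and -0.04 (99.67 and 1.64) and ERK feedback and output genes -0.04 and 0.14 (0.41 and 100). In the same order, the array labelled vehicle had medians of 0.13, 0.26, 0.02 and 0.24 (percentiles 100, 100, 91.9 and 100). It thus lay on the side of estradiol in ERK genes and on that of ERα17p in the other lists. Of the treated arrays only the ERα17p array stood apart in YAP and SRF targets (median 0.09, percentile 100), G1/S genes (0.06, 99.5), p53 targets (0.06, 98.96) and GPER-responsive genes (0.06, 98.6). Of these, YAP and SRF targets (0.05, 98.94), p53 targets (0.13, 99.92) and GPER-responsive genes (1.37, 100) also lay high on the array labelled vehicle. Other genes off the baseline by 1.5-fold were DLX3 (-0.61), HOXC13 (-0.66) and EDN2 (-0.62) on the estradiol array, and HMOX1, SLC7A11, CXCL11 (0.77) and TCIM (0.66), which were higher on the ERα17p array. The mirror-image pairs of values mean that these arrays entered the median that forms the baseline, and with it as reference the differences of both treatments correlated at -0.17, so opposite sides can in part mirror each other.

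Of the tests that follow, those of a lowering by both treatments, of second probe sets, of the ID genes and of mixed RNA were chosen only after the result was seen. The first pattern is the height of NF-kB targets on the array labelled vehicle. Leukocyte RNA is argued against: 17 leukocyte markers differed from the mean of both treated arrays by a median of -0.0118 (spread 0.15, highest 0.31). From that mean, 31 ERBB2 amplicon and luminal genes differed by an absolute median of 0.107 (spread 0.09, largest 0.63). Of the 31, 2 were at least 1.5-fold apart. These values argue against a cell line under that label that differs in such genes. A line alike in them, or a partial mixture, was not covered. Artefacts on single probe sets without regard to the gene were examined by the third test tried, whose rule asked for more than every random draw. Where a listed gene's first probe set lay at least 1.5-fold above that mean, the second did too in 5 of 6 cases. The highest of 10000 random draws was 3. The order of probe sets is arbitrary, and with it exchanged 5 of 8 passed against at most 5, which fell short of the rule. Such artefacts are thus argued against in 1 order only, for listed genes with 2 or more probe sets. Genes with 1 probe set, such as CCL20, CXCL1, TNF and CXCL3, were not covered. The share of listed genes above both treated arrays on all their probe sets had decided nothing at 36.4% (4 of 11; 12.5% of all genes), since 50% was wrongly foreseen for an artefact, and a count of listed genes had only restated the pattern. What also stays open is a stimulus in the vehicle culture, from handling or a wrong label. It may also have raised immediate early genes (median 0.75 over 28 genes). A lowering by both treatments, from a vehicle level of 1.28 to -0.06 and 0.09, stays open too. The outcome set for it, a vehicle median near the baseline with treated medians well below it, was not met. Only a lower median on the array labelled vehicle would have argued against it. The pattern that prompted the test excluded that outcome, so the test decided nothing. With 1 vehicle array the stimulus and the lowering cannot be told apart.

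The second pattern is the low level of ID1 to ID4 on the estradiol array. A scale difference between the arrays would move all genes alike. All 19775 genes had a median difference of -0.0125 (spread 0.13) and 41 were lower by 1.5-fold, when ID1 to ID4 had a median of -1.14. The deposited values thus held no common shift of that size. RMA normalises by quantiles, which sets such a median near 0 in advance. The test therefore decided nothing about the arrays before normalization. Centring, tried first, hardly moved any value and decided nothing either. Of 9 probe sets 7 (77.8%) lay at least 1.5-fold below the ERα17p array, which decided nothing about an artefact on single probe sets, since the genes were picked for being low and only 2 have more than 1 probe set. That explanation stays open, as do an effect of estradiol and a difference between single cultures, which were not tested.

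The third pattern is the partial NF-kB signal on the ERα17p array. If the estradiol array stood for the unmixed ERα17p profile, vehicle RNA mixed into the ERα17p sample would give every gene 1 mixing fraction, whereas 16 of 37 genes at least 4-fold higher on the array labelled vehicle than on the estradiol array (43.2%) excluded the median fraction of 1.80% by more than 2 times the noise of a difference (0.13 log2 units), with implied values from -8.60 to 24.1%. The unmixed profile was not measured, so mixing stays open. A weak response of these genes to ERα17p, or a smaller dose of whatever acted on the vehicle culture, is a hypothesis that was not tested.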
